A study of Homo sapiens with 33 samples.

How the data were processed

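NB4 cells, an established human acute promyelocytic leukaemia line, were grown untreated, with DMSO or with 1 µM ATRA, and per the labels' protocols medium with fresh drug was added on day 3. Other cell lines that the growth protocol names were not analysed here. Total RNA was extracted on columns with DNase treatment, and stranded total RNA libraries were sequenced as 150 bp paired ends on a HiSeq 3000, per the labels' protocols. Each group held 3 biological replicates. The group and the replicate number (2, 4 and 5) were taken from the sample titles. Per the labels each replicate was sequenced in 2 technical runs, and the table used here holds 1 column per library, so runs were not compared.
The values are raw fragment counts per gene, which the authors made with featureCounts 1.5.1 in strand-specific paired-end mode, per the file headers. A fragment that overlapped several genes was counted in each of them, per the file headers, so overlapping genes on 1 strand share counts. The annotation merged Ensembl and FANTOM CAT gene models on GRCh38, with the genome sequence of Ensembl release 90. Trimmomatic 0.36, STAR 2.5.2b and Subread 1.5.1 are named in the submitters' processing notes. The deposited table held 85160 genes, 58970 with Ensembl and 26190 with FANTOM CAT identifiers, and the latter took 0.458% of the counts. Gene symbols and types came from GENCODE 29, in which 57447 of the Ensembl identifiers had a match, and coordinates are those of the deposited table. Of all genes, 20374 (23.9%) share exon sequence with another gene on the same strand, and of the 12703 protein-coding genes with over 330 counts in all libraries together 43.8%. Of other genes named, TNFRSF1B shares 16.8%, BCL2A1 16.1%, ITGB3 16%, BTG1 14.8%, CD38 12.7%, SERPINB2 12.1%, FCGR2A 11.4%, CYP26A1 10.7% and DEFA4 10.6% of its exon length with another gene. Genes with near-identical copies (NCF1, HBA1, histones, defensins) and the overlapping mitochondrial models are given as uncertain. Protein-coding genes took 82.73% of the counts and mitochondrial and small RNA genes 11.73%. Library totals ran from 18341456 to 33490654 fragments.
Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (22971 genes), libraries were scaled by TMM with factors from 0.827 to 1.108, and 1 quasi-likelihood model with a mean per group was fitted to all 33 libraries, so that groups shared an estimate of the spread (biological coefficient of variation 0.077, prior degrees of freedom 15.93). Contrasts were ATRA against DMSO at each time, DMSO at each time against untreated cells, and the change of the ATRA effect between times (12 h minus 4 h, 24 h minus 12 h, 72 h minus 24 h, 120 h minus 72 h and 120 h minus 4 h). P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The standard error of a log2 fold change is the one implied by the F statistic. CPM used TMM-scaled library sizes, and log CPM a prior count of 2. Where a group had 0 counts the fold was bounded against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% interval. Floors and intervals cover counting error only.
Gene lists were fixed before the data were examined. They were retinoid metabolism and direct targets, azurophil granule proteins, specific and gelatinase granule proteins, NADPH oxidase, mature myeloid surface receptors and integrins, myeloid transcription factors, stem and progenitor genes, S phase, mitosis, replication-dependent histones, cell cycle inhibitors, ribosome biogenesis, cytosolic ribosomal proteins, interferon-stimulated genes, chemokines and inflammatory cytokines, coagulation and fibrinolysis, the BCL2 family, cholesterol synthesis, glycolysis and hypoxia, amino acid starvation and the unfolded protein response, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, lysosome and autophagy, chromatin regulators, and markers of monocytes and macrophages, of eosinophils, basophils and mast cells, of erythroid cells and megakaryocytes, of lymphocytes, and of epithelium and fibroblasts. Lists with at least 5 tested members (28) were tested with camera in limma 3.58.1 on voom values with an estimated correlation, and p-values were adjusted over the lists of a comparison. Of 420 list tests 65 passed, and 219 with a preset correlation of 0.01. All 65 are among the 219.
The named genes followed a rule fixed before the data were examined. It took the 6 rising and 6 falling genes of largest fold change at each ATRA comparison, and 4 and 4 for the others, among called genes with a symbol and an average log2 CPM of at least 1, without overlap between groups for ATRA and DMSO comparisons. It also took a core set (CYP26A1, DHRS3, RARB, TGM2, CEBPE, CD38, ITGAM, ITGAX, CSF3R, NCF1, CYBB, MPO, ELANE, MYC, CCL2, TNFSF10 and MKI67) and up to 4 members of smallest p from each list described. ELANE had 160 counts in all libraries together and was not tested. Results for some genes that the rule took are not reported here, and these genes are left out of the counts of named genes under the alternatives.
The steps were tested on simulated data. For ATRA against DMSO at 24 h, with 21613 genes and 50 changed genes at each fold, 44, 66, 82 and 94% of genes changed 1.5, 2, 4 and 8-fold were recovered. Of 155 calls 12 were false (7.7%), and a simulated comparison without change gave 3 calls. Of 20 unchanged lists 0 passed camera. Changed genes were few beside the 24.7 to 70.6% of genes called in the real ATRA comparisons, and genes were drawn independently of each other. The simulation thus does not show how scaling and list tests do in the real setting.
Alternatives planned beforehand were DESeq2 1.42.0, limma-voom, RLE size factors, no filter on low counts, only the groups compared, the replicate number as a block, mitochondrial and small RNA genes left out, each library left out in turn, and for lists a preset correlation and fry. Alternatives with DMSO replicate 2 of 72 h left out of the other comparisons and with the mean of DMSO at 24 h and 120 h in the place of 72 h were chosen after seeing the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9. All 0, 4 and 12 h libraries ran in lane 4. At 24, 72 and 120 h replicate 2 ran in lane 2 and replicates 4 and 5 in lane 3.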

Results

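RNA was measured over a time course in NB4 cells, an established line of acute promyelocytic leukaemia, a leukaemia in which myeloid cells stop maturing at the promyelocyte stage. Cells received 1 µM all-trans retinoic acid (ATRA), the vitamin A derivative used to make such cells mature, or the solvent DMSO, and were collected after 4, 12, 24, 72 and 120 h. Untreated cells were collected at 0 h. Each of the 11 groups held 3 libraries from separate biological replicates, numbered 2, 4 and 5, which gave 33 libraries in all. The total count per library ran from 18341456 to 33490654 fragments, with a median of 25927472. Of 85160 genes in the table, 22971 had enough counts to be tested. Libraries of 1 group correlated with each other at 0.9855 or above across genes on the log scale. The first principal component held 56.2% of the variance, and along it the ATRA libraries of 72 h and 120 h stood apart from all others. The study searched for drugs for differentiation therapy, and the comparisons here ask what ATRA changed at each time, how that change moved between times, and how DMSO cultures differed from the untreated start. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over 3 libraries, and log2 fold changes with their standard error. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera with an estimated correlation.

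**Figure D1:**
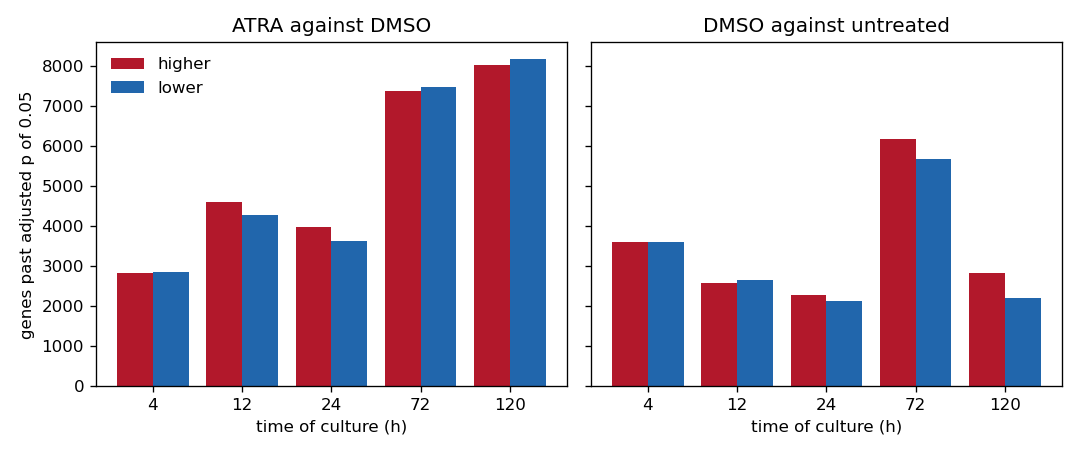
Genes past the threshold in each comparison of ATRA with DMSO and of DMSO with untreated cells, drawn by direction. ATRA calls ran from 5673 at 4 h to 16207 at 120 h, and DMSO calls were most numerous at 72 h, with 11854.

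After 4 h of ATRA, genes of retinoid handling rose. DHRS3, which encodes a retinaldehyde reductase, stood at 69.6 ± 2.55 against 1.71 ± 0.555 CPM (ATRA first, DMSO second, as in all such pairs; log2 change 5.33 ± 0.13; ENSG00000162496, GRCh38 chromosome 1, 12563025 to 12657618). On the same log2 scale, which holds for every change given without a unit, the transcriptional repressor gene HIC1 rose by 4.79, ASB2, an E3 ligase adaptor gene, by 3.87, the transglutaminase gene TGM2 by 4.69 and CD38, a surface enzyme of maturing myeloid cells, by 2.10. In the list of retinoid metabolism and direct targets, 15 of 18 tested members rose and 1 fell (15 and 1 adjusted over the list alone), and the list passed its test (adjusted p = 2.23e-05). NCF1, a subunit of the phagocyte NADPH oxidase with near-identical pseudogenes and therefore uncertain, stood at 105 ± 7.88 against 5.81 ± 0.666 CPM (4.17). RARB, a retinoic acid receptor gene, had 1 count in the DMSO libraries together, and its ratio was 36.9 (counting interval 6.26 to 1490). The retinoic acid hydroxylase gene CYP26A1 rose by 1.89, at 1.06 ± 0.0628 against 0.283 ± 0.0573 CPM.
The largest rises at 4 h among genes the naming rule took were, beside DHRS3, RHBDL3 (6.14), SCUBE1 (6.04), the helix-loop-helix inhibitor ID1 (5.97), PTGES (5.32), a prostaglandin E synthase gene that shares 21.7% of its exon length with another gene, and the myeloid kinase gene FGR (5.25). The largest falls by the same rule were SH3TC1 (-2.96), PLD6 (-2.68), the insulin receptor substrate IRS1 (-2.62), tissue factor F3 (at 4.53 ± 0.206 against 25.6 ± 0.669 CPM), RAB7B (-2.39) and the prostaglandin receptor PTGER4 (-2.39). Every later ranking of genes over a whole comparison is by this rule too, and genes of lower counts can have changed more. Stem and progenitor genes fell. In that list 0 of 16 tested members rose and 11 fell (0 and 11 adjusted over the list alone, list test adjusted p = 1.3e-05), with MYC at 125 ± 3.06 against 420.4 ± 42.1 CPM (-1.75 ± 0.08), MYB at -1.72 and the telomerase gene TERT at -1.20. Of ribosome biogenesis genes, 0 of 30 tested members rose and 26 fell (0 and 28 adjusted over the list alone, list test adjusted p = 0.0341), among them NOP16 (-0.68) and WDR43 (-0.61). Without replicate 4 of DMSO at 4 h that list did not pass, with an adjusted p of 0.0515. The myeloid regulators CEBPE (1.94) and IRF1 (2.26) rose, while in their list 11 of 27 tested members rose and 8 fell (11 and 9 adjusted over the list alone, list test adjusted p = 0.551 with an estimated correlation). The oxidase subunit gene CYBB (-0.16), the granule peroxidase gene MPO (-0.12), the death ligand gene TNFSF10 (-0.17) and the proliferation marker MKI67 (0.14) did not pass at 4 h, though CYBB did without DMSO replicate 5 of 4 h (adjusted p = 0.0236). In all 5673 genes passed, 2820 higher and 2853 lower, and 1387 of them changed at least 2-fold. Of these calls 5312 (93.6%) had all 3 libraries of one group above all 3 of the other. Chance gives 10% for genes not chosen for a difference, which is no baseline for called genes, here and at the other times.
After 12 h the NADPH oxidase, the enzyme complex of the phagocyte burst, and surface receptors of mature myeloid cells had risen. CYBB stood at 700.4 ± 15.6 against 288 ± 6.62 CPM (1.28 ± 0.08). Among oxidase genes 7 of 8 tested members rose and 1 fell (7 and 1 adjusted over the list alone, list test adjusted p = 0.014). Of the receptors and integrins 22 of 30 tested members rose and 0 fell (22 and 2 adjusted over the list alone, list test adjusted p = 0.014), among them ITGAX (3.16 ± 0.12), the receptor gene for granulocyte colony-stimulating factor CSF3R (2.28), ITGAM (2.44) and TNFRSF1B (2.07). Retinoid genes stayed high, and 16 of 18 tested members rose and 1 fell (16 and 1 adjusted over the list alone, list test adjusted p = 0.000303), with PRAM1 at 4.18 and CD38 at 2.85. The eosinophil-attracting chemokine CCL24 (ENSG00000106178, GRCh38 chromosome 7, 75810823 to 75823369) stood at 37.9 ± 1.93 against 0.0813 ± 0.00628 CPM (8.77) and TGM2 at 243 ± 16.1 against 1.44 ± 0.528 CPM. SMIM35 rose by 7.30. PELATON and RHBDL3 each had 1 count in the DMSO libraries together, with ratios of 561 (counting interval 100 to 22200) and 359 (counting interval 64.0 to 14200), intervals that cover counting error only. ARL14EPL was among the largest rises too, but its exons lie wholly within another gene on its strand, so its counts are uncertain.
The largest falls at 12 h by the naming rule were the secreted liver-type factor FGL1 (-4.43), TAMALIN (-3.72), the aryl hydrocarbon target CYP1B1 (-2.98), at 17.9 ± 0.953 against 140.5 ± 4.32 CPM, the BMP antagonist NOG (-2.82), GSAP (-2.79) and SPRY4 (-2.77). NPR1, of lower counts, had an estimate of -5.23. Its mean ATRA level was 0.077 CPM with the prior count of 2, near the floor, so the size of that fall is uncertain. Lists of biosynthesis fell. All 30 ribosome biogenesis genes were lower (30 also adjusted over the list alone, list test adjusted p = 0.024), with NCL at 689.6 ± 24.0 against 1115 ± 25.6 CPM and RRP9 at -0.93. Of genes of amino acid starvation and the unfolded protein response 2 of 24 tested members rose and 18 fell (3 and 19 adjusted over the list alone, list test adjusted p = 0.014), led by the amino acid transporter SLC7A5 (-1.75) and the chaperone CALR (-0.93). Of cholesterol synthesis genes 0 of 23 tested members rose and 14 fell (0 and 14 adjusted over the list alone, list test adjusted p = 0.0345). Of stem and progenitor genes 0 of 16 tested members rose and 9 fell (0 and 10 adjusted over the list alone, list test adjusted p = 0.0104), and MYC stood at -0.38, a smaller fall than at 4 h by a tested difference of 1.37 ± 0.11. MPO fell by 0.58 on the log2 scale. In total 8888 genes passed, 4600 higher and 4288 lower, 2412 of them by at least 2-fold. The groups did not overlap for 8393 (94.4%) of the calls (10% for genes not so chosen).
After 24 h some granule genes of immature granulocytes had risen. The defensin gene DEFA4 stood at 188 ± 13.2 against 3.06 ± 0.224 CPM (5.95 ± 0.11) and BPI, a bactericidal granule protein, at 31.1 ± 2.14 against 0.192 ± 0.116 CPM (7.46), among the 6 largest rises. In the azurophil granule list 10 of 16 tested members rose and 4 fell (10 and 4 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.35 with an estimated correlation). CST7 fell by 2.23 on the log2 scale within it. HIC1 (7.38; ENSG00000177374, GRCh38 chromosome 17, 2053877 to 2065815), TGM2 (7.54) and CCL24 (7.53) were also among those 6, and the actin-associated PALLD, with 2 counts in DMSO, had a ratio of 255 (counting interval 70.1 to 2110). Retinoid genes rose as a list (13 of 18 tested members rose and 1 fell, 14 and 1 adjusted over the list alone, list test adjusted p = 0.000354), and so did the oxidase genes (6 of 8 tested members rose and 1 fell, 6 and 1 adjusted over the list alone, list test adjusted p = 0.0238). Of surface receptors 16 of 30 tested members rose and 4 fell (17 and 4 adjusted over the list alone), without passing as a list (adjusted p = 0.101 with an estimated correlation). Of ribosomal protein genes 15 of 30 tested members rose and 0 fell (18 and 0 adjusted over the list alone), by small amounts such as 0.35 for RPL3 (adjusted p = 0.569 with an estimated correlation).
Falls at 24 h were led by the cytokine-like CYTL1 (3.46 ± 0.347 against 119.6 ± 2.90 CPM; -5.11), the scavenger receptor STAB1 (-4.86), FGL1 (-6.39), TAMALIN (-5.22) and GSAP (-4.95). The acyl-CoA synthetase ACSL6 had 2 counts in ATRA, and its DMSO to ATRA ratio was 178 (counting interval 49.0 to 1480). Of stem and progenitor genes 0 of 16 tested members rose and 13 fell (0 and 13 adjusted over the list alone, list test adjusted p = 0.000354), with GATA2 at -1.77 and TERT at -1.57. The anti-apoptotic BCL2 fell by 2.48 on the log2 scale and its relative BCL2A1 rose by 4.73. JUN (-2.70) and TNF (-2.27) were lower, CEBPE (2.55) and CCL2 (3.24 ± 0.12) higher. MPO (-0.19) and MKI67 (-0.20) did not pass. MKI67 passed with DESeq2 (adjusted p = 0.0196), limma-voom (0.0458), RLE size factors (0.0224), the replicate number as a block (0.0308), mitochondrial and small RNA genes left out (0.0498) and the groups compared alone (0.00187, MPO 0.00368), and without DMSO replicate 4 (0.0356) or ATRA replicate 5 (0.0489) of 24 h or DMSO replicate 2 of 72 h (0.0458). In the coagulation list the median log2 change was 0.78 and the mean 0.54, while camera ranked it downward (adjusted p = 0.958). At this time 7624 genes passed, 3986 higher and 3638 lower, 2342 of them by at least 2-fold, with no overlap between groups for 7384 (96.9%, and 10% for genes not so chosen). From 24 h on, replicate 2 was sequenced in lane 2 and replicates 4 and 5 in lane 3, which left too few libraries for a test within lane 2. With the replicate number as a term over all 33 libraries, 7934, 15024 and 16353 genes passed at 24, 72 and 120 h. That term is shared with 0, 4 and 12 h, where all replicates ran in lane 4, so it does not adjust for the lane.

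**Figure D2:**
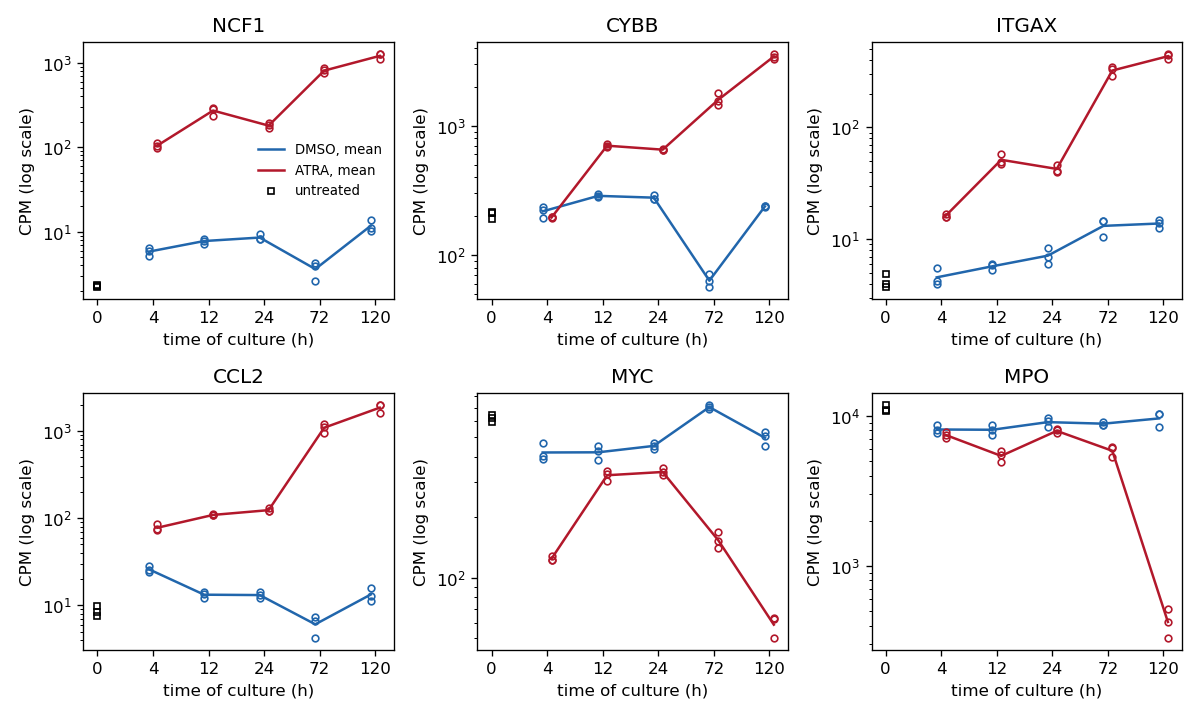
CPM on a log scale for NCF1, CYBB, ITGAX, CCL2, MYC and MPO in each library against time, with time points evenly spaced and not to scale, for untreated, DMSO and ATRA cells. CCL2 in ATRA reached a mean of 1092 CPM at 72 h and 1855 CPM at 120 h, and MPO in ATRA lay at 422.9 CPM at 120 h.

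After 72 h interferon-stimulated and inflammatory genes were high in ATRA. All 34 interferon-stimulated genes rose (34 also adjusted over the list alone), with a median log2 change of 5.52 (adjusted p = 0.00953). The antiviral gene IFIT3 stood at 839 ± 111 against 6.09 ± 0.377 CPM (7.10 ± 0.11), OAS1 at 7.35, OAS2 at 8.57 and the RNA sensor RIGI at 878 ± 123 against 21.2 ± 0.552 CPM. The guanylate-binding GBP4, which shares 19.7% of its exon length with another gene, and its relative GBP1P1 had no count in DMSO at 72 h and were at least 131-fold and 125-fold higher against a floor of 3 counts over the group. Among chemokines and inflammatory cytokines 22 of 25 tested members rose and 1 fell (22 and 1 adjusted over the list alone, list test adjusted p = 0.0486), with the monocyte chemoattractant CCL2 at 1092 ± 133 against 6.05 ± 1.67 CPM (7.50 ± 0.14) and the neutrophil chemoattractant CXCL8 at 1272 ± 178 against 43.0 ± 7.76 CPM. The cytokine LIF (10.58; ENSG00000128342, GRCh38 chromosome 22, 30234352 to 30257992), TNFSF15 (10.45) and PTGES (10.18), which shares 21.7% of its exon length with another gene, were among the 6 largest rises. TNFSF10 rose by 3.67. Of monocyte and macrophage markers 10 of 12 tested members rose and 1 fell (10 and 1 adjusted over the list alone, list test adjusted p = 0.0471), with MERTK at 4.27 and CD86 at 6.99. The chemokine list no longer passed without replicate 5 of DMSO at 72 h (0.0514) or replicate 4 of ATRA at 72 h (0.0501), nor did the monocyte list without that DMSO library (0.0514). With RLE size factors the adjusted p was 0.0539 for each of the 2 lists.
Phagocyte genes rose with them at 72 h. All 8 oxidase genes were higher (8 also adjusted over the list alone, list test adjusted p = 0.0144), with CYBB at 1582 ± 179 against 63.8 ± 7.44 CPM (4.63 ± 0.09). CYBB in DMSO was itself lower at 72 h than at 24 h, by a log2 change of -2.126, and with the mean of DMSO at 24 h and 120 h in the place of 72 h, a choice made after seeing the data, its change was 2.62 and the list's adjusted p 0.0394. Other changes of 72 h that this choice moved by over 1.5-fold included CCL2 (6.37), IFIT3 (5.91), TNFSF10 (3.00), PTGES (11.21), CD86 (6.21), MERTK (5.12), BPI (9.76), DEFA4 (6.29), CST7 (-6.38), CTSG (-5.69), CHST13 (-5.65) and CYTL1 (-9.25). Of surface receptors and integrins 28 of 30 tested members rose and 1 fell (28 and 1 adjusted over the list alone, list test adjusted p = 0.00953), among them SIRPA (3.31), ITGAX (4.62) and ITGB2 (2.88). Of retinoid genes 16 of 18 tested members rose and 1 fell (16 and 1 adjusted over the list alone, list test adjusted p = 0.00709), and ICAM1, an adhesion molecule, reached 3684 ± 406 against 74.5 ± 17.1 CPM. RARB stood at 3.72 ± 0.428 against 0.394 ± 0.647 CPM, where the DMSO counts were 25, 1 and 0 in replicates 2, 4 and 5 and 51.3% of its exon length lies opposite TOP2B. Granule genes went both ways, with BPI (8.09) and DEFA4 (5.43) higher and CST7 (-7.35) and the protease CTSG (-6.69) lower. CYTL1 (-8.26), STAB1 (-7.72) and CHST13 (-6.25) were among the other large falls. Of stem and progenitor genes 3 of 16 tested members rose and 11 fell (3 and 11 adjusted over the list alone, list test adjusted p = 0.0357, lost with RLE size factors at 0.0516), MYC at 154 ± 14.2 against 707 ± 15.6 CPM and TERT at -4.23. Growth lists were lower gene by gene without passing as lists in the main fit. In ribosome biogenesis 1 of 30 tested members rose and 29 fell (1 and 29 adjusted over the list alone, list test adjusted p = 0.0544 with an estimated correlation), in mitosis 0 of 30 tested members rose and 29 fell (0 and 30 adjusted over the list alone, list test adjusted p = 0.204 with an estimated correlation). With the mean of DMSO at 24 h and 120 h in the place of 72 h, ribosome biogenesis passed camera (adjusted p = 0.0331) and mitosis did not (0.117). In total 14873 genes passed, 7383 higher and 7490 lower, 7010 of them by at least 2-fold. Groups did not overlap for 14292 (96.1%) of the calls (10% for genes not so chosen).
After 120 h genes for proteins of the late granules, of lysosomes and of the phagocyte surface were high, and several primary granule genes were low. MPO, the peroxidase of primary granules, stood at 423 ± 93.5 against 9624 ± 1060 CPM (-4.51 ± 0.12; ENSG00000005381, GRCh38 chromosome 17, 58269755 to 58280935). MS4A3 (-6.47) and CST7 (-6.18) fell as well, while BPI (8.74) stayed up. In the azurophil list 6 of 16 tested members rose and 10 fell (6 and 10 adjusted over the list alone, list test adjusted p = 0.413 with an estimated correlation). Of specific and gelatinase granule proteins 14 of 16 tested members rose and 1 fell (14 and 1 adjusted over the list alone, list test adjusted p = 0.00536), with the chitinase-like CHI3L1 at 1457 ± 18.4 against 144 ± 12.8 CPM and QPCT at 5.71. Of lysosome and autophagy genes 26 of 28 tested members rose and 1 fell (26 and 1 adjusted over the list alone, list test adjusted p = 0.00971), with CTSS at 4.49 and SQSTM1 at 1978 ± 144 against 85.9 ± 3.15 CPM. Of surface receptors 29 of 30 tested members rose and 0 fell (29 and 0 adjusted over the list alone, list test adjusted p = 0.00536), with the formyl peptide receptor FPR2 at 7.86 and SIRPA at 4.48, and all 8 oxidase genes rose (8 also adjusted over the list alone, list test adjusted p = 0.0098), CYBB to 3409 ± 146 against 238 ± 2.49 CPM. TGM2 reached 6165 ± 414 against 2.59 ± 0.134 CPM (11.21). Of retinoid genes 15 of 18 tested members rose and 2 fell (16 and 2 adjusted over the list alone, list test adjusted p = 0.00971), and CYP26A1 (0.93) did not pass. CYP26A1 passed with the replicate number as a block (adjusted p = 0.0472), with RLE size factors (0.0364), and without DMSO replicate 5 (0.0203) or ATRA replicate 4 (0.0407) of 120 h. GPR82, with 1 count in DMSO, had a ratio of 9850 (counting interval 1770 to 389000), and DAAM2 and the calcium-binding S100A12, with none, were each at least 599-fold higher. FFAR3, LILRA5 and ARPIN were among the largest rises but share 39.6%, 56.8% and 92% of their exon length with other genes.
Inflammatory genes stayed high at 120 h. All 34 interferon-stimulated genes rose (34 also adjusted over the list alone; median 6.20; adjusted p = 0.00973), IFI6 to 2480 ± 321 against 13.6 ± 1.51 CPM. Of chemokines and cytokines 22 of 25 tested members rose and 1 fell (23 and 1 adjusted over the list alone, list test adjusted p = 0.0388), with IL1B at 7.53, CXCL8 at 3595 ± 162 against 66.6 ± 7.61 CPM and CCL2 at 7.13 ± 0.14. Of monocyte and macrophage markers 11 of 12 tested members rose and 0 fell (11 and 0 adjusted over the list alone, list test adjusted p = 0.0178), CD86 at 7.50. In the BCL2 family 12 of 14 tested members rose and 1 fell (12 and 1 adjusted over the list alone, list test adjusted p = 0.0178), BCL2A1 up by 9.09 and BCL2 at 2.08 ± 0.255 against 80.2 ± 4.14 CPM (-5.28). Of stem and progenitor genes 2 of 16 tested members rose and 12 fell (2 and 13 adjusted over the list alone, list test adjusted p = 0.00536), MYC at -3.09 ± 0.09, TERT at -6.93 and GATA2 at -4.40. ZBTB16 (-8.97) and CYTL1 (-8.92) had large falls. The defensin DEFB1 had no count in ATRA and was at least 72.1-fold lower. The pseudogenes GOLGA8CP and GOLGA8DP, members of a family of near-identical copies, were lower too and are uncertain. Of ribosome biogenesis genes 1 of 30 tested members rose and 29 fell (1 and 29 adjusted over the list alone, list test adjusted p = 0.041), with NOLC1 at -1.97. MKI67 fell to 197 ± 24.0 against 372 ± 8.71 CPM, all 30 S-phase genes fell (30 also adjusted over the list alone, list test adjusted p = 0.0524 with an estimated correlation), MCM6 by 2.62 on the log2 scale, and so did all 30 mitosis genes (30 over the list alone, list test adjusted p = 0.08), BUB1B by 2.18.
The other lists did not pass as lists at 120 h. Adjusted p-values with an estimated correlation were 0.21 for replication-dependent histones, of which all 30 were lower (30 adjusted over the list alone) and which have near-identical copies, 0.121 for cytosolic ribosomal proteins, of which 0 of 30 tested members rose and 29 fell (0 and 30 adjusted over the list alone), and 0.165 for myeloid transcription factors, of which 20 of 27 tested members rose and 6 fell (20 and 6 adjusted over the list alone). BCL6 rose by 6.25 and ID2 by 4.87. Of cell cycle inhibitors 10 of 18 tested members rose and 4 fell (10 and 4 adjusted over the list alone, list test adjusted p = 0.299), with CDKN2D at 2.51, and of coagulation genes 8 of 11 tested members rose and 3 fell (8 and 3 adjusted over the list alone, list test adjusted p = 0.21), with PLAUR at 3.64 and THBD at 3.79. Of cholesterol genes 10 of 23 tested members rose and 6 fell (10 and 6 adjusted over the list alone, list test adjusted p = 0.707), of glycolysis and hypoxia genes 9 of 25 tested members rose and 13 fell (9 and 13 adjusted over the list alone, list test adjusted p = 0.761), and of amino acid and unfolded protein genes 9 of 24 tested members rose and 13 fell (9 and 13 adjusted over the list alone, list test adjusted p = 0.587). Of nuclear-encoded oxidative phosphorylation genes 5 of 26 tested members rose and 15 fell (5 and 15 adjusted over the list alone, list test adjusted p = 0.587). In its mitochondrially encoded part, which is uncertain because gene models overlap, 0 of 13 tested members rose and 3 fell (0 and 1 adjusted over the list alone, list test adjusted p = 0.81). Of chromatin regulators 12 of 27 tested members rose and 12 fell (12 and 12 adjusted over the list alone, list test adjusted p = 0.81), with PADI4 at 5.87. For glycolysis and for chromatin regulators the median (-0.17 and -0.13) and the test pointed down and the mean (0.07 and 0.15) up. Markers of other cells moved too. Of eosinophil, basophil and mast cell markers 4 of 12 tested members rose and 6 fell (4 and 7 adjusted over the list alone, list test adjusted p = 0.587), with the eosinophil protein CLC at 138 ± 17.1 against 0.245 ± 0.123 CPM and EPX at -2.01. Of lymphocyte markers 5 of 8 tested members rose and 2 fell (5 and 2 adjusted over the list alone, list test adjusted p = 0.452), and of epithelial and fibroblast markers 3 of 8 tested members rose and 3 fell (3 and 3 adjusted over the list alone, list test adjusted p = 0.961), where the median was 0.00, the mean 1.17 and the test pointed down. Of erythroid and megakaryocyte markers 3 had counts enough, 1 of which, ITGB3 (3.04), rose (1 also adjusted over the list alone), too few for a list test. In total 16207 genes passed at 120 h, 8022 higher and 8185 lower, 9612 of them by at least 2-fold. Groups did not overlap for 15467 (95.4%) of the calls (10% for genes not so chosen).

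**Figure D3:**
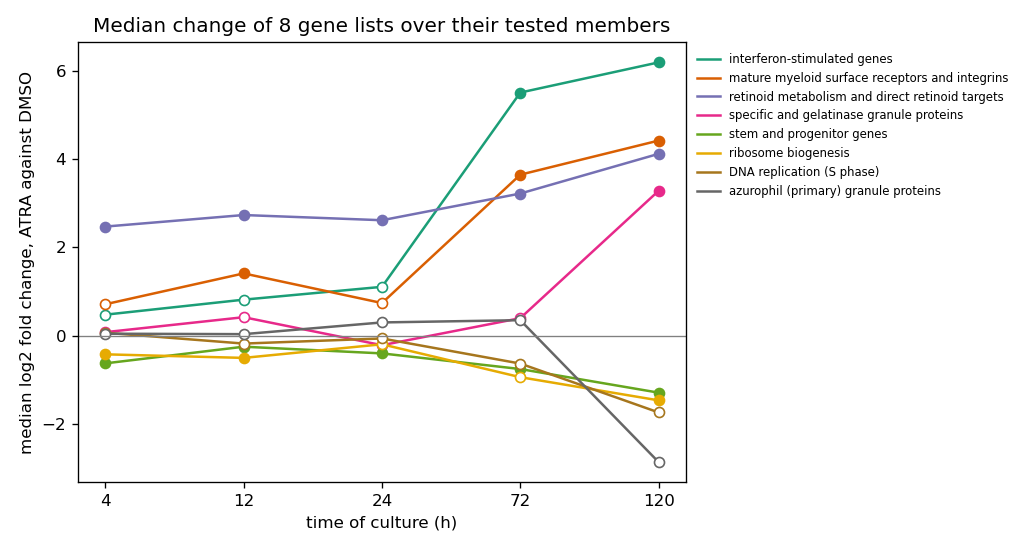
Median log2 fold change of ATRA against DMSO for 8 gene lists over the 5 times, with times evenly spaced and not to scale and filled points where the list's adjusted p was under 0.05. The median of interferon-stimulated genes was 0.475 at 4 h, without passing, and 5.52 at 72 h.

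The change of the ATRA effect between times was tested directly. From 4 h to 12 h receptors and oxidase genes gained, with ITGAM by 1.76 ± 0.15 and CYBB by 1.44. Among receptors 15 of 30 tested members rose and 0 fell (17 and 0 adjusted over the list alone, list test adjusted p = 0.0399) and among oxidase genes 5 of 8 tested members rose and 0 fell (6 and 0 adjusted over the list alone, list test adjusted p = 0.0399). By the naming rule HK3 (4.29), CCL24 (3.97), the defensin pseudogene DEFA8P (3.86) and DEFA4 (3.49) gained most, and HES2 (-4.93), TAMALIN (-2.93) and CNR2 (-2.85) lost most beside UCN2, which shares 53.7% of its exon length. Stem and progenitor genes, lower at 4 h, gained, with MYB at 1.64. In their list 4 of 16 tested members rose and 2 fell (7 and 2 adjusted over the list alone, list test adjusted p = 0.0399). Retinoid genes gained (8 of 18 tested members rose and 0 fell, 10 and 1 adjusted over the list alone, list test adjusted p = 0.0473) and amino acid and unfolded protein genes lost (1 of 24 tested members rose and 11 fell, 1 and 15 adjusted over the list alone, list test adjusted p = 0.0399). The retinoid call was lost without DMSO replicate 5 at 4 h (0.0946) or DMSO replicate 2 at 12 h (0.0632) and the amino acid call without DMSO replicate 2 at 4 h (0.0598) or ATRA replicate 2 at 12 h (0.0541). With the replicate number as a block they stood at 0.058 and 0.0528. In total 3222 genes passed, 1868 upward and 1354 downward.
From 12 h to 24 h cholesterol genes gained and specific granule genes lost. Of cholesterol genes 18 of 23 tested members rose and 0 fell (19 and 0 adjusted over the list alone, list test adjusted p = 0.000258), with HMGCS1 at 1.14 ± 0.13 and LSS at 0.99, and of specific and gelatinase granule genes 0 of 16 tested members rose and 5 fell (1 and 6 adjusted over the list alone, list test adjusted p = 0.0156), with MMP9 at -1.78 and FCN1 at -1.71. By the naming rule BPI (3.37) and FBN1 (2.22) gained most beside DEFA3 and DEFA1B, defensin genes of near-identical sequence and therefore uncertain. The intermediate filament gene VIM (-3.04), ASGR2 (-2.98) and ID1 (-2.85) lost most by that rule, as did ACSL6, whose ATRA level at 24 h rests on 2 counts. Here 1584 genes passed, 574 upward and 1010 downward. Fitted to the groups compared alone, 1104 passed upward and 1132 downward.
From 24 h to 72 h all 34 interferon-stimulated genes gained (34 also adjusted over the list alone, list test adjusted p = 0.00831), IFIT3 by 6.18 ± 0.14. TNFSF10 gained 4.14, CXCL8 5.90 and IL1B 6.25. Among chemokines 19 of 25 tested members rose and 0 fell (20 and 0 adjusted over the list alone, list test adjusted p = 0.028), among receptors 24 of 30 tested members rose and 0 fell (24 and 0 adjusted over the list alone, list test adjusted p = 0.00934) and among oxidase genes 7 of 8 tested members rose and 0 fell (7 and 0 adjusted over the list alone, list test adjusted p = 0.0147). With the mean of DMSO at 24 h and 120 h in the place of 72 h, where DMSO itself had moved, the oxidase list had a median gain of 0.72 in place of 1.23 (adjusted p = 0.0451), and IFIT3 gained 4.99, IL1B 5.57 and TNFSF10 3.46. CTSG (-5.20) and CST7 (-5.12) had the largest losses by the naming rule (-4.20 and -4.14 with that choice). Of coagulation genes 7 of 11 tested members rose and 0 fell (7 and 0 adjusted over the list alone, list test adjusted p = 0.0452), SERPINB2 at 7.34, a call lost without DMSO replicate 5 at 72 h (0.053) and with RLE size factors (0.0534). In total 10551 genes passed, 4933 upward and 5618 downward.
From 72 h to 120 h specific granule and lysosome genes gained and several primary granule genes lost. Of specific and gelatinase granule genes 11 of 16 tested members rose and 2 fell (11 and 2 adjusted over the list alone, list test adjusted p = 0.000473), with CHI3L1 at 3.28 ± 0.10 and SLPI at 2.80, and of lysosome genes 25 of 28 tested members rose and 0 fell (25 and 0 adjusted over the list alone, list test adjusted p = 0.0034), with ASAH1 at 2.91 and CTSB at 1.85. MS4A3 (-5.74), PRTN3 (-4.75) and MPO (-3.91) lost, and in the azurophil list 3 of 16 tested members rose and 10 fell (4 and 10 adjusted over the list alone, list test adjusted p = 0.0564 with an estimated correlation). Stem and progenitor genes lost further (1 of 16 tested members rose and 11 fell, 1 and 11 adjusted over the list alone, list test adjusted p = 0.00305), where GATA2 fell by 3.24. With the mean of DMSO at 24 h and 120 h in the place of 72 h, MS4A3 stood at -4.83, PRTN3 at -3.72 and ASAH1 at 2.25, and the azurophil list passed camera (adjusted p = 0.0378). The hormone gene STC1 (-8.05, and -11.39 with that choice) and RNU6ATAC (-5.97, and -4.05 with that choice) were among the 4 largest losses. RNU6ATAC is named for a small nuclear RNA, but its gene model runs from 134148235 to 134172084 on chromosome 9. Its counts need not come from that RNA and are uncertain. IGSF6 reached 101 ± 8.96 against 0.0274 ± 0.0474 CPM in ATRA and DMSO at 120 h. The count was 9021, 4016 upward and 5005 downward. The larger side turned with RLE size factors, to 4651 upward and 4312 downward, and with DESeq2, to 4470 and 4129.
From 4 h to 120 h all 30 S-phase genes (30 also adjusted over the list alone, list test adjusted p = 0.0377) and all 30 mitosis genes (30 over the list alone, list test adjusted p = 0.0443) lost, MCM6 at -2.62 ± 0.11 and BUB1B at -2.17. Of receptors 26 of 30 tested members rose and 0 fell (26 and 0 adjusted over the list alone, list test adjusted p = 0.00744), of lysosome genes 26 of 28 tested members rose and 1 fell (26 and 1 adjusted over the list alone, list test adjusted p = 0.00869) and of specific granule genes 9 of 16 tested members rose and 1 fell (9 and 1 adjusted over the list alone, list test adjusted p = 0.00744). All 34 interferon-stimulated genes (34 over the list alone, list test adjusted p = 0.008) and all 8 oxidase genes (8 over the list alone, list test adjusted p = 0.0119) gained. The call for chemokines (18 of 25 tested members rose and 3 fell, 18 and 3 adjusted over the list alone, list test adjusted p = 0.0474) was lost without DMSO replicate 5 at 4 h (0.0625) or at 120 h (0.0541), with RLE size factors (0.0594) and with the replicate number as a block (0.0644). RLE size factors moved the median of all genes by 0.109, from -0.064 to 0.044, in this comparison, and the changes given are relative to the TMM median. Here 12902 genes passed, 6018 upward and 6884 downward.
Across times, 1151 genes were higher at all 5 times and 970 lower, 3244 were called in both directions at different times, and 3288 of the 22971 were never called. Calls of 4 h and 12 h shared 1935 higher genes, where independent lists of these sizes would share 565, and 1799 lower ones against 533. Calls of 72 h and 120 h shared 5850 higher genes against 2578 and 5803 lower ones against 2669. The log2 changes of 4 h and 120 h correlated at 0.448 and those of 72 h and 120 h at 0.824 across genes, which are not independent replicates. No library entered more than 1 of these times. Of the genes higher at 12 h, 471 had a lower log2 change at 24 h past the test of that difference, and 304 of these gained again by 72 h. Over all 22971 genes tested, 4933 gained from 24 h to 72 h. The libraries of 12 h and of 24 h each enter more than 1 of the tests that chose the 304, with opposite signs, which alone favours such a pattern. Genes of the PCDHG cluster, with near-equal values, count separately among the 304.
DMSO cultures were compared with the untreated cells of 0 h to show what changed in culture without ATRA. Untreated cells were collected only at 0 h, so an effect of the solvent and one of time in culture cannot be told apart. All DMSO comparisons share the same untreated libraries, so a level particular to those libraries would appear as a change at every time. After 4 h several immediate-early genes were far lower than at 0 h. Such genes respond within minutes to handling and serum, and they were not tested as a list. FOS stood at 1.48 ± 0.594 against 73.3 ± 2.13 CPM in DMSO against untreated (-5.61 ± 0.14; ENSG00000170345, GRCh38 chromosome 14, 75277285 to 75292138), EGR2 at -5.60, FOSB at -5.17 and EGR1 at -4.88. EGR3 (-5.57) shares 21.2% of its exon length with another gene. CXCL8 (-2.91) and TNF (-2.44) were lower, CCL2 (1.60) and NCF1 (1.36) higher. ATP2B2 (3.16), LRRC49 (2.70) and ADGRG5 (2.54) were among the 4 largest rises. Of cholesterol genes 0 of 23 tested members rose and 18 fell (0 and 20 adjusted over the list alone, list test adjusted p = 0.00832), with INSIG1 at 62.8 ± 2.20 against 255 ± 1.00 CPM. Of azurophil granule genes 0 of 16 tested members rose and 13 fell (0 and 13 adjusted over the list alone, list test adjusted p = 0.0326), MS4A3 at -0.56 and MPO at -0.46. Stem and progenitor genes fell (1 of 16 tested members rose and 11 fell, 1 and 13 adjusted over the list alone, list test adjusted p = 0.00508), BCL11A by 1.26 on the log2 scale. All 30 ribosomal protein genes were lower by small amounts (median -0.31; 30 over the list alone, list test adjusted p = 0.312 with an estimated correlation). Of cell cycle inhibitors 2 of 18 tested members rose and 10 fell (2 and 10 adjusted over the list alone, list test adjusted p = 0.0429), BTG1 at -1.58, a call lost without DMSO replicate 2 (0.0541), 4 (0.0504) or 5 (0.0648) of 4 h. In total 7208 genes passed, 3596 higher and 3612 lower, without overlap between groups for 6515 (90.4%, and 10% for genes not so chosen).
After 12 h FOS (-5.25), FOSB (-6.02) and EGR2 (-5.96) stood as low against 0 h, with TNF at -2.84. EGR3 had a log2 change of -7.93. LRRC49 (3.35), TEDC2-AS1 (2.46) and the kinase DYRK1B (2.07) rose most beside LINC01355, whose exons lie within another gene. Of cholesterol genes 0 of 23 tested members rose and 20 fell (0 and 21 adjusted over the list alone, list test adjusted p = 0.000565), with HMGCS1 at 55.9 ± 4.63 against 145 ± 8.68 CPM (-1.38 ± 0.09) and INSIG1 at -1.77. Of amino acid and unfolded protein genes 1 of 24 tested members rose and 13 fell (1 and 14 adjusted over the list alone, list test adjusted p = 0.0383), ATF3 at -1.77 and XBP1 at -0.70. That call was lost without DMSO replicate 2 of 12 h (0.0591) and with RLE size factors (0.054). All 30 ribosomal protein genes were lower against the same untreated libraries (median -0.29; 30 over the list alone, list test adjusted p = 0.259 with an estimated correlation). MPO (-0.47) and MYC (-0.56) were lower. The count was 5208, 2565 higher and 2643 lower, without overlap for 4965 (95.3%, and 10% for genes not so chosen).
After 24 h FOS (-5.33), FOSB (-6.37), EGR2 (-6.33) and TNF (-2.65 ± 0.11) remained below 0 h, and EGR3 had 3 counts in DMSO, an untreated to DMSO ratio of 427 (counting interval 146 to 2070). LRRC49 (2.87) rose. NCF1 (1.90), CD38 (0.66) and CHI3L1 (159.6 ± 8.55 against 90.4 ± 2.68 CPM) were higher, the protease CTSG (-1.18) lower. MT-TY and MT-TC, transfer RNA genes of overlapping mitochondrial models, were among the largest rises and are uncertain. All 30 ribosomal protein genes were lower (median -0.33; 30 over the list alone, list test adjusted p = 0.126 with an estimated correlation). With camera and an estimated correlation 0 of 28 lists passed at 24 h and at 72 h, with 7 and 4 at an unadjusted p under 0.05. A preset correlation of 0.01 gave 11 and 9 lists, and fry 16 and 21. In total 4390 genes passed, 2267 higher and 2123 lower, without overlap for 4166 (94.9%, and 10% for genes not so chosen). DMSO libraries of 24, 72 and 120 h were sequenced in lanes 2 and 3 and the untreated ones in lane 4. Against 0 h, time and lane therefore cannot be told apart at 24 h, 72 h and 120 h. Between DMSO at 72 h and the mean of DMSO at 24 h and 120 h, which shared its lanes, 11717 genes were called. That comparison was chosen after seeing the data, and it does not free the changes from 0 h to 72 h of the lane.
After 72 h of DMSO many hypoxia and glycolysis genes were higher and many S-phase genes lower than at 0 h, without either list passing. The stress-response gene NDRG1 stood at 126 ± 11.3 against 6.53 ± 1.24 CPM (4.24 ± 0.12), the regulatory kinase of glycolysis PFKFB4 at 3.18 and the mitophagy receptor BNIP3 at 2.38. Of glycolysis and hypoxia genes 21 of 25 tested members rose and 3 fell (21 and 3 adjusted over the list alone, list test adjusted p = 0.119 with an estimated correlation). Of S-phase genes 1 of 30 tested members rose and 28 fell (1 and 28 adjusted over the list alone, list test adjusted p = 0.119 with an estimated correlation), PCNA at 128 ± 10.6 against 352 ± 2.67 CPM. Of cholesterol genes 19 of 23 tested members rose and 2 fell (20 and 2 adjusted over the list alone, list test adjusted p = 0.119 with an estimated correlation), HMGCS1 at 1.97. CCNG2, a cyclin gene of cell cycle exit, rose to 32.2 ± 2.59 against 5.65 ± 0.814 CPM, and DHRS3 by 2.59. COL5A1 (4.56) and VLDLR-AS1 (4.39) rose most beside HSPA6, whose exons overlap those of another gene, and FOS (-3.89), FOSB (-4.90) and TNF (-4.02) stayed low. Abundant small RNA genes took 9.38, 11.2 and 10.8% of the counts in these libraries and 6.99 to 8.06% in the untreated ones. Replicate 2 held 41 features over 4 times higher than in both other libraries of its group, where the next, with 9, 7 and 4, were replicate 2 of DMSO at 24 h and 4 h and of untreated cells. The count was 11854, 6188 higher and 5666 lower, without overlap for 11328 (95.6%, and 10% for genes not so chosen). With the mean of DMSO at 24 h and 120 h in the place of 72 h, a choice made after seeing the data, it was 4649.
After 120 h of DMSO cholesterol and glycolysis genes were higher than at 0 h. Of cholesterol genes 22 of 23 tested members rose and 0 fell (22 and 0 adjusted over the list alone, list test adjusted p = 3.1e-05), with HMGCS1 at 759 ± 16.1 against 145 ± 8.68 CPM (2.39 ± 0.09) and MVD at 1.83. Of glycolysis and hypoxia genes 22 of 25 tested members rose and 0 fell (24 and 0 adjusted over the list alone, list test adjusted p = 0.00156), with PFKFB4 at 3.12 and NDRG1 at 54.6 ± 2.91 against 6.53 ± 1.24 CPM. LINC03040 (4.59), the adaptor NEDD9 (4.53) and HIF1A-AS3 (4.52) rose most beside FCGR2B, which shares 58.9% of its exon length. Surface receptors CR1 (2.11), FCGR2A (1.95) and ITGAX (1.70) were higher, and in their list 12 of 30 tested members rose and 3 fell (15 and 3 adjusted over the list alone, list test adjusted p = 0.167 with an estimated correlation). The cell cycle inhibitor CDKN1A (2.31) and the histamine-synthesis gene HDC (1.80) rose, and TNFSF10 rose by 0.72. FOSB (-4.69), FOS (-3.51), EGR3 (-3.29) and SOCS3 (-2.91) were lowest against 0 h. Of ribosome biogenesis genes 0 of 30 tested members rose and 20 fell (0 and 24 adjusted over the list alone, list test adjusted p = 0.144 with an estimated correlation). The count was 5024, 2824 higher and 2200 lower (56.2% higher), and DESeq2 put the share at 44.8% higher. Groups did not overlap for 4868 (96.9%) of the calls (10% for genes not so chosen). Without DMSO replicate 5 of 120 h the count was 3214.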

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

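The tests of carry-over, of lane and of medium for DMSO at 72 h, and of exchanged libraries and of retinoid signalling for the 24 h pattern, were chosen only after the result was seen.
Features high in DMSO replicate 2 of 72 h formed the first pattern, with 41 features over 4 times higher than in both other libraries of its group, 39 of which have an exon on the opposite strand. The next libraries were replicate 2 as well, of DMSO at 24 h and 4 h and of untreated cells, with 9, 7 and 4 such features, of which 9, 7 and 3 were among the 41. MT-TA, a mitochondrial gene of the light strand, stood at 9643, 4187 and 5858 CPM in these libraries and 6835 in DMSO replicate 2 of 72 h, against 208.3 to 5042 elsewhere. MT-TA is itself among the 41 and thus no separate evidence. ATRA replicate 5 of 120 h, at 5042 CPM, and DMSO replicate 2 of 12 h, at 4121, held 0 such features. Carry-over from another library of this series is argued against, since replicate 2 stood at a median of 4.977 times the highest library of the other groups (interval 1.74 to 7.2). Residual genomic DNA is argued against too, since 3951 low-count genes without an opposite exon had a median log2 ratio of -0.103 (-0.129 to -0.079) to the mean of the other replicates. Fragments counted on the wrong strand may be a source and stay open, with a median log2 ratio of 0.365 (-0.049 to 0.953) over 60 low-count genes opposite abundant ones, short of the bound of 1 set beforehand, and no biological explanation was tested.
ATRA effects that moved against their 12 h direction by 24 h and back by 72 h formed the second pattern, with 521 genes, 304 of them higher and 217 lower in ATRA at 12 h, and 201 of opposite sign at 24 h. Genes of the PCDHG cluster entered separately with near-equal values, such as PCDHGA1 (0.532 at 12 h, -0.703 at 24 h) and PCDHGA2 (0.547, -0.71). A fragment over several genes counts in each, so such genes may share counts. The libraries of 12 h and of 24 h each enter neighbouring tests of this choice with opposite signs, which alone favours such a pattern. Against an exchange of the 12 h and 24 h ATRA libraries, those of 12 h correlated better with the 4 h effects (0.615 to 0.642 against 0.496 to 0.518, a gap of 0.097), but they did so with the 120 h effects too (0.493 to 0.519 against 0.463 to 0.492) and overlapped for 72 h (0.558 to 0.578 and 0.552 to 0.573), so that an exchange stays open. The lane changed between 12 h and 24 h in the same way for ATRA and DMSO libraries, so a shift common to both cancels in the ATRA minus DMSO effects. A lane shift that differed between ATRA and DMSO stays open. The median shift in DMSO was -0.034 against 0.495 in ATRA, a fraction of -0.068, under the bound set beforehand, but that bound was wrong, because the genes were chosen by the ATRA minus DMSO difference. Lower retinoid signalling at 24 h may play a part and stays open, as the retinoid list did not pass for that change (adjusted p = 0.277).
The DMSO libraries of 72 h stood apart from untreated cells and from DMSO at 24 h and 120 h, the pattern of most called genes among DMSO comparisons. The lane as whole cause is argued against, since 11717 genes were called between DMSO at 72 h and the mean of DMSO at 24 h and 120 h, which shared its lanes. The counts of small RNA genes themselves as whole cause are argued against, since 11637 genes were called against untreated cells without mitochondrial and small RNA genes. Leaving these genes out keeps any difference in the other genes that came with the higher share of small RNA, so that test cannot decide on such a difference. Medium spent by 72 h and renewed on day 3 might contribute and stays open, as glycolysis and hypoxia genes did not pass between 72 h and 120 h (adjusted p = 0.873, median 0.062, interval -0.149 to 0.192).
Other results were listed because the effect at 2 times had opposite signs and the test of the difference passed. The ATRA effect on TNFSF10 differed by 4.057 between 12 h and 72 h, by 4.158 between 12 h and 120 h, by 4.141 between 24 h and 72 h and by 4.242 between 24 h and 120 h, each as the later minus the earlier log2 change, and its call at 12 h was lost with limma-voom (adjusted p = 0.139), with the replicate number as a block (0.0592) and without DMSO replicate 2 (0.149) or 4 (0.0628) or ATRA replicate 2 (0.105) or 5 (0.102) of 12 h, that at 24 h with limma-voom (0.0721) and without DMSO replicate 4 (0.0569) or ATRA replicate 2 (0.0544) of 24 h. For MKI67 the ATRA effect of 120 h minus that of 12 h was -1.131, and its call at 12 h was lost under 9 alternatives (adjusted p 0.0551 to 0.259), among them DESeq2, RLE size factors and without DMSO replicate 4 or 5 or ATRA replicate 2 or 4 of 12 h. Among DMSO changes from untreated cells, MYC at 72 h minus 4 h, 12 h and 24 h gave 0.749, 0.746 and 0.641, and at 120 h minus 72 h -0.507, where the call at 72 h was lost with DESeq2 (adjusted p = 0.0591), RLE size factors (0.0506), no filter (0.0549) and without any 1 of the 6 libraries compared (0.0541 to 0.218). For CCL2 these were -2.114, -1.138 and -1.117, and 1.142, and its call at 72 h was lost without untreated replicate 4 (0.0582) or DMSO replicate 5 of 72 h (0.12). For TNFSF10, 120 h minus 4 h, 12 h, 24 h and 72 h gave 1.958, 1.673, 1.451 and 1.402. CYBB at 72 h minus 12 h and 24 h gave -2.172 and -2.126, and at 120 h minus 72 h 1.902, where the call at 120 h was lost with RLE size factors (adjusted p = 0.0779), no filter (0.0651), and without untreated replicate 4 or 5 or any 1 DMSO library of 120 h (0.0539 to 0.213). CEBPE at 120 h minus 72 h gave 0.667. Over the genes of the cholesterol list in DMSO the median change was 1.45 from 4 h to 120 h and 1.561 from 12 h to 120 h.
For every comparison the 6 libraries, or the 6 pairs for a change between times, make 10 splits, which cannot give a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. In fits of the compared groups alone the real splits of ATRA against DMSO called 4206, 8379, 8370, 14059 and 14764 genes at 4, 12, 24, 72 and 120 h, those of DMSO against untreated cells 5083, 5209, 4841, 11565 and 5468, and those of the changes between times 2519 (12 h minus 4 h), 2236 (24 h minus 12 h), 10915 (72 h minus 24 h), 8816 (120 h minus 72 h) and 12091 (120 h minus 4 h). The highest other split called 0 genes with edgeR in each of them. At an unadjusted p under 0.05 the highest other splits held 578, 753, 587, 137 and 151 genes for ATRA, 906, 1616, 2751, 168 and 765 for DMSO, and 338, 751, 299, 230 and 134 for the changes. Other tools were not run on the splits.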

How the results depend on the processing

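The alternatives with the mean of DMSO at 24 h and 120 h in the place of 72 h, and without DMSO replicate 2 of 72 h in the fit of other groups, were chosen only after the data were seen. Counts of called genes stayed within 1.5 times under DESeq2 (ratio 0.95 to 1.135), limma-voom (0.99 to 1.035), RLE size factors (0.957 to 1.081), no filter (0.796 to 1.05), only the groups compared (0.705 to 1.412), mitochondrial and small RNA genes left out (0.976 to 1.024) and without DMSO replicate 2 of 72 h elsewhere (0.992 to 1.031). With the replicate number as a block the counts ran from 1755 to 16353 (ratio 1.009 to 1.108). The numbers were not treated as pairing, since not every pair was over 0.1. Same-numbered ATRA and DMSO libraries correlated at -0.019 to 0.2 in their deviations (4 of 15 pairs over 0.1, 10 of 15 best with their own number, a hint from the data, and all 3 at 12 h and at 120 h) and DMSO and untreated ones at -0.06 to 0.141 (1 and 7 of 15, all 3 at 4 h). The alternative with each technical run alone was not run, as the table holds 1 column per library. With RLE size factors the larger direction of calls turned for ATRA against DMSO at 12, 24, 72 and 120 h, for DMSO against untreated cells at 24 and 120 h and for the last 3 changes between times. Depth limits genes of a few counts, whose folds are bounds or ratios with counting intervals.
Without 1 library, 119 of 120 counts stayed within 1.5 times. ATRA against DMSO gave 4729 to 5471 genes at 4 h, 7773 to 8240 at 12 h, 6580 to 7010 at 24 h, 13973 to 14426 at 72 h and 15746 to 15967 at 120 h. DMSO against untreated cells gave 6001 to 6912, 4016 to 4502, 3083 to 4072, 10761 to 11087 and 3214 to 4511, the value of 3214 without DMSO replicate 5 of 120 h. Changes of the ATRA effect gave 2630 to 3875 (12 h minus 4 h), 1223 to 1578 (24 h minus 12 h), 9757 to 10277 (72 h minus 24 h), 8370 to 8753 (120 h minus 72 h) and 12572 to 12720 (120 h minus 4 h). Of 3360 list tests without 1 library 15 were lost and 65 gained. With RLE size factors 59 of 420 list tests passed, against 65, with the block 66, with a preset correlation 219 and with fry 287. Under fry the direction opposed the median for myeloid transcription factors at 24 h (-0.155) and chromatin regulators at 72 h (-0.164) and 120 h (-0.134). Genes called in the same direction at 2 or more times numbered 14734, and 6231 with a 2-fold change as well. Of 19569 values for 438 named genes 19028 were called in the same direction in both fits or called in neither. Of the others 430 lost the call, 66 gained it and 45 did not keep their direction. Changes of direction among values called in neither fit were not counted. The cause was not tested for these.
With the mean of DMSO at 24 h and 120 h in the place of 72 h, which leaves no 72 h library in DMSO against untreated cells, 4649 genes were called there in place of 11854, and of 112 list tests 14 gained the call and 0 lost it. Log2 changes that turned in that comparison were RARB -0.007, CEBPE 0.266, CYBB 0.324, MYC -0.388, CCL2 0.615, UBA7 -0.086, AZU1 -0.118, PTX3 -0.465, HP 0.279, LMO2 0.237, FEN1 0.003, RRM2 0.122, CCND3 0.152, BTG1 -0.174, RPL3 -0.269, RPL13 -0.227, RPL4 -0.236, NDUFB3 0.003, GAA -0.108, EZH2 0.069, DNMT3B 0.187, CSF1R 0.373, APOE -0.77, EPOR -0.416, CD4 -0.219, CD79B -0.015 and ACTA2 -0.424. For ATRA at 72 h they were H2BC17 -0.051, MT-CYB -0.372, MT-CO2 -0.304, ITGA2B 0.447, EPOR 0.344 and ACTA2 0.437. For the change from 24 h to 72 h they were DHRS3 0.54, CEBPE -0.354 and MKI67 -0.551, and from 72 h to 120 h DHRS3 -0.58, RARB -0.517, NCF1 0.344, CYBB 1.219 and CCL2 0.752, while CD38 went to 0. All these genes were called in the main fit, in the changed one or in both. Among genes called in neither, RARB went from -2.473 to 1.953 for the change from 24 h to 72 h. ITGAX went from 0.348 to -0.043 for that from 72 h to 120 h. The log2 fold change of COL1A1, DMSO at 12 h against untreated at 0 h, turned to 0.289 without untreated replicate 2, and was lowest at -3.556 without untreated replicate 4. The log2 fold change of COL1A1, DMSO at 24 h against untreated at 0 h, turned to 0.358 and was lowest at -3.485 without the same libraries. The log2 fold change of RARB, change of the ATRA effect, 120 h minus 72 h, turned to -0.027 without DMSO replicate 2 of 72 h and was highest at 5.814 without DMSO replicate 5 of 120 h.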
